A study of Mus musculus with 15 samples.

How the data were processed

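RNA was sequenced from isolated PDGFRβ-positive cells of mouse brain in 15 libraries: 3 from wild-type (WT) sham mice, 4 from miR-210 knockout (KO) sham mice, 4 from WT mice 24 h after neonatal hypoxia-ischemia (HI) and 4 from KO mice 24 h after HI. Per the labels, total RNA was extracted with a column kit for small samples and the libraries were made by a commercial service. The labels name genotype, treatment and a replicate number. They do not say whether replicates are separate animals or whether the libraries were made in more than 1 batch. The p-values of single genes thus measure the spread between samples. List tests with a preset correlation and the test of gene positions compare genes with other genes and do not measure that spread alone.

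The authors deposited a table of expected counts, estimated reads per gene, without normalization. Its header names no unit; the unit was read from the values, of which 3.12% to 3.92% per library were not whole numbers, and from RSEM among the tools listed. Per the submitters' processing notes the tools were HISAT2 2.1.0, Bowtie2 2.4.4, Bowtie (no version), RSEM 1.3.1 and DESeq2 1.4.5 with the build mm39, and neither the role nor the order of each tool is given in the sources used here. The table ended at 65535 lines, of which 17892 carried values in all 15 columns and 47643 were blank in all 15. The table may have been shortened, so a gene without values is not shown to be unexpressed. Of the lines with values, 17862 were matched to a gene symbol and 17841 to a protein-coding gene. The 3318 lines matched to long non-coding RNAs were blank. The list of nuclear-retained RNAs and the list of mitochondrially encoded genes had no values and were not analysed here.

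Expected counts were rounded to whole numbers, and 14853 genes that passed the edgeR function filterByExpr were tested. Total counts ran from 15436376 to 18118697 per library. A fold against a group at 0 in every library was bounded with a floor of 3 counts per library, which covers counting error only. One fit of 4 group means over the 15 libraries was made with edgeR 4.0.16 (TMM normalization, glmQLFit and glmQLFTest) in R 4.3.3. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in each of 5 contrasts: HI against sham in WT, HI against sham in KO, KO against WT in sham, KO against WT after HI, and the difference between the HI responses of KO and WT. The biological coefficient of variation was 38.6%. On data simulated from these libraries, 100 genes with a 4-fold change were recovered at 92%, 88%, 86% and 91% in the 4 pairwise contrasts. In the difference of responses 67% were recovered. At 2-fold the shares were 47%, 62%, 40%, 55% and 12%. The simulation gave all groups the same spread per gene, drew genes independently and changed only genes above a set mean level. In the real libraries KO replicates differed more than WT replicates, with chi-square per degree of freedom of 44.6 to 384 against 11.3 to 46.7. The first principal component held 57.9% of the variance, so genes did not vary independently. The shares are thus likely too high for these data, above all in contrasts with KO.

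Before the data were examined, 34 gene lists, the contrasts, the tests, the rule for named genes and most alternative settings were fixed. Of the lists, 31 had at least 5 tested genes and were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists, with an estimated correlation and fry beside it. Fry asks whether a list changed at all, not whether it changed more than other genes. The fry p-values were not adjusted over the lists. The sex-linked list had 4 tested genes, all on the Y chromosome, and had no set test; their log2 fold changes lay between -0.60 and 0.86 in the 4 pairwise contrasts, each with a standard error above its size. For each list the members called over all genes are given beside those called with p adjusted over the list alone.

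The named genes followed a fixed rule. The targeted gene came first, then the 10 largest positive and the 10 largest negative log2 fold changes per pairwise contrast among genes with adjusted p under 0.05, at least a 2-fold change, groups that did not overlap in CPM (edgeR, counts scaled to the normalized library size) and a mean of at least 10 CPM in the higher group, without provisional symbols. For the difference of responses the rule took the 10 smallest p-values among called genes. Each list added up to 4 members with the smallest p. A gene named outside this rule is said to be so. Log2 fold changes are given with the standard error derived from the edgeR test, CPM values with the SD over libraries.

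Genes with a match to the miR-210-3p seed in the annotated 3-prime UTR were found in a mouse reference of the assembly GRCm38, an older build than that of the authors, used for gene names, UTR sequence and gene order. They were compared with genes that have an annotated UTR and no match, and with 59 other 7mers of the same base composition.

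The alternative settings fixed in advance were size factors by RLE, DESeq2 1.42.0, limma-voom with sample quality weights, no filter, a filter of at least 1 CPM in 3 libraries, a fit of only the 2 groups compared, the replicate number as a block, and leaving out each library in turn. After seeing the data, 3 more were added: a fit without the 5 libraries with the highest neuron markers (a mean above 2.5 log2 CPM), and fits with neural and choroid marker levels, with or without microglia marker levels, as covariates. Other splits of the libraries into groups of the same sizes were run for each count of genes and lists. Figures were drawn with matplotlib 3.10.9 and Python 3.11.15.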

Results

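The cells were isolated for PDGFRβ, a receptor carried by pericytes, vascular smooth muscle cells and fibroblasts of the brain. Total expected counts were 17695039, 17539492 and 17911825 in WT sham libraries 1, 2 and 3, and 15436376, 17017223, 17306041 and 17270145 in KO sham libraries 1, 3, 4 and 6. They were 17865974, 17277866, 17541081 and 17556218 in WT HI libraries 1, 2, 4 and 5, and 18118697, 17184893, 16291948 and 17915204 in KO HI libraries 1 to 4. The targeted gene, Mir210, had 1 line in the table and no value in any library, so its loss in KO mice could not be checked, and the blank line does not show absence of the transcript; the mature microRNA was not measured.

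Pericyte, endothelial and microglial transcripts were all abundant in these libraries, and their balance differed between genotypes. The 20 pericyte markers averaged 7.70 ± 0.28 log2 CPM in WT sham (SD, n = 3), 6.79 ± 0.73 in KO sham (n = 4), 7.66 ± 0.22 in WT HI (n = 4) and 6.40 ± 0.67 in KO HI (n = 4). Pdgfrb itself (Gene ID 18596) ran from 688 to 987 CPM in WT sham, 251 to 785 in KO sham, 751 to 1049 in WT HI and 194 to 596 in KO HI libraries. Endothelial markers averaged 9.03 ± 0.12, 8.38 ± 0.67, 9.03 ± 0.14 and 7.99 ± 0.49 log2 CPM in the same order, and microglia markers 7.26 ± 0.26, 7.93 ± 0.37, 6.80 ± 0.66 and 8.65 ± 0.48. Neuron markers were uneven within groups: they averaged 6.30 log2 CPM in KO sham 1, 5.67 in KO HI 3, 3.93 in KO sham 3, 3.74 in KO HI 2 and 2.97 in WT sham 2, and between 0.06 and 1.97 in the other 10 libraries. Ttr, the main transcript of the choroid plexus, took 5.17% of the counts in KO HI 2 and 2.65% in KO sham 3.

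**Figure D1:**
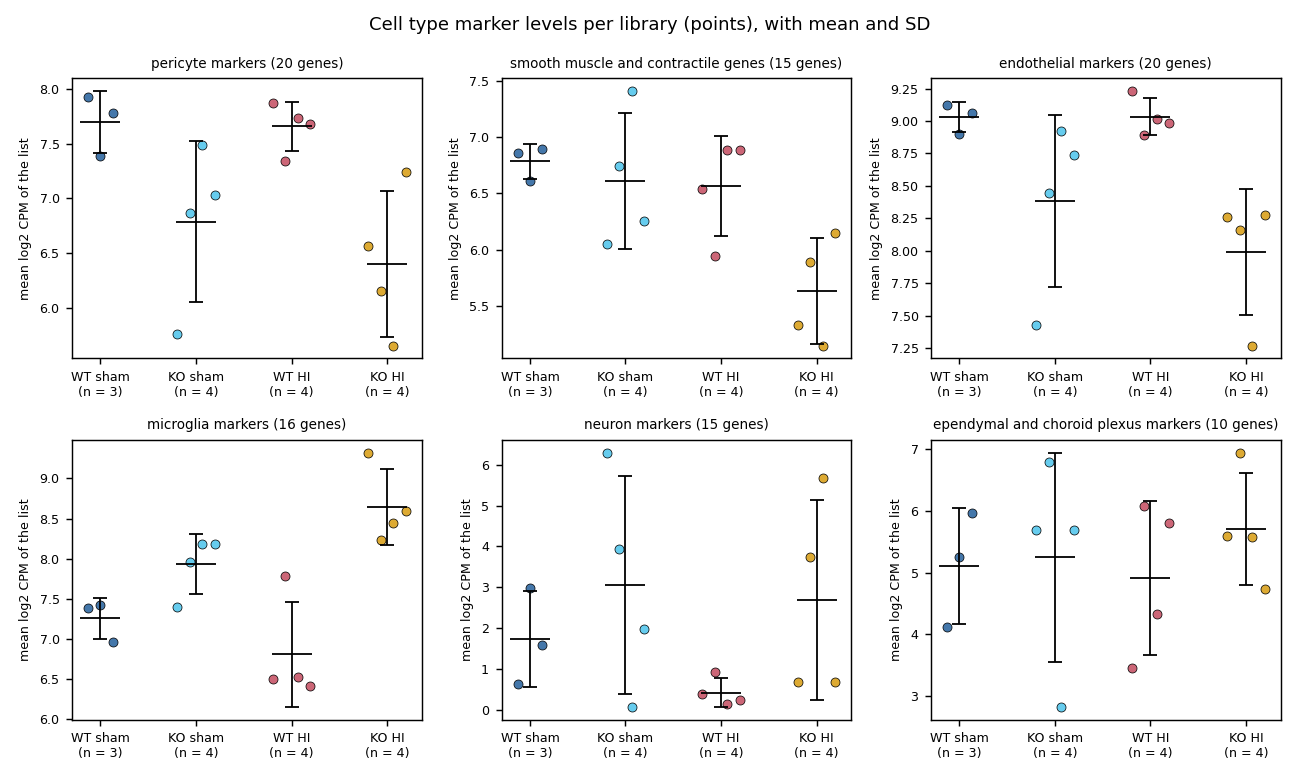
Mean log2 CPM of 6 marker lists in each library (points), with the group mean and SD (bars), for WT sham (n = 3), KO sham, WT HI and KO HI (n = 4 each). Microglia markers averaged 8.65 in KO HI and 6.80 in WT HI, while neuron markers ranged from 0.06 to 6.30 across libraries.

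The first comparison asked what HI did to these cells in WT mice after 24 h. The 10 largest increases in WT were of secreted, adhesion and matrix proteins. Lcn2 (Gene ID 16819), an iron-binding acute-phase protein, went from 1.48 ± 0.57 to 111 ± 9.39 CPM (SD, n = 3 and 4), and Lrg1 (Gene ID 76905), a modulator of TGF-β signalling in vessels, from 0.82 ± 0.12 to 65.7 ± 11.8 CPM. The leukocyte adhesion receptors Selp and Sele rose by 5.95 ± 0.64 and 5.23 ± 0.49 log2 units, and the eosinophil chemokine Ccl11 by 6.92 ± 0.92. The acute-phase genes Saa3 (6.61 ± 0.93), Itih4 (6.68 ± 1.05) and Serpina3n (5.29 ± 1.04), the cytokine Il11 (6.17 ± 0.96) and the matrix protein Spp1 (5.74 ± 1.13) completed the 10 largest increases, each with groups that did not overlap. The pericyte, smooth muscle, fibroblast and endothelial lists did not pass the set test (camera adjusted p = 0.678, 0.216, 0.988 and 0.955). Neutrophil and monocyte markers had a median of 1.16, and 0 of 14 were called over all genes (2 up adjusted over the list alone). As a set they had a camera adjusted p = 0.00187, and adjusted p = 0.660 with an estimated correlation.

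Of 27 cytokine, chemokine and NF-κB target genes 10 rose (19 adjusted over the list alone), with Ccl5 at 4.28 ± 0.50, Il1rn, the antagonist of interleukin-1, at 4.20 ± 0.65 and Ptgs2, the inducible cyclooxygenase, at 2.71 ± 0.36 log2 units. The list's camera adjusted p was 8.78e-26, and adjusted p = 0.0585 with an estimated correlation. Of 19 matrix proteases and inhibitors 6 rose (8 adjusted over the list alone), among them Timp1 (3.27 ± 0.32) and the collagenase Mmp13 (4.37 ± 0.87); this list kept its call with an estimated correlation (camera adjusted p = 1.51e-15, and 0.032 with an estimated correlation). The stromelysin Mmp3 had 1, 0 and 0 counts in WT sham and 111 to 215 counts in WT HI libraries. Of 19 lysosome and phagocytosis genes 4 rose (10 adjusted over the list alone): Lgals3, Cd63, Lpl and Spp1, with Cd63 at 0.77 ± 0.12 and Lgals3 at 3.38 ± 0.42 log2 units. Lysosome and phagocytosis genes as a set had a camera adjusted p = 3.07e-10, and adjusted p = 0.207 with an estimated correlation.

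The p53 list rose as a set (camera adjusted p = 7.69e-05, and 0.032 with an estimated correlation), with 1 of 17 members called, Phlda3 at 1.34 ± 0.23 (5 adjusted over the list alone). Genes near Mir210 also kept their call with an estimated correlation (camera adjusted p = 0.00277, and 0.032 with an estimated correlation), with 1 of 34 called (4 adjusted over the list alone), the interferon-induced Ifitm1 at 2.38 ± 0.37; Ifitm1 was also the only called member of the pericyte list. Of 28 hypoxia-inducible genes 1 rose, Ddit4 at 0.89 ± 0.20 (3 adjusted over the list alone). Hypoxia-inducible genes as a set had a camera adjusted p = 0.0295, and adjusted p = 0.207 with an estimated correlation. Of 20 genes of the integrated stress and unfolded protein response 1 rose, Xbp1 at 0.91 ± 0.19 (3 adjusted over the list alone). Stress response genes as a set had a camera adjusted p = 0.00193, and adjusted p = 0.427 with an estimated correlation. Of 24 interferon-stimulated genes Zbp1 and Ifi27l2a (1.69 ± 0.33) rose (3 up and 1 down adjusted over the list alone). Interferon-stimulated genes as a set had a camera adjusted p = 0.00119, and adjusted p = 0.674 with an estimated correlation.

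Some genes fell in WT. The cell cycle list had a median of -0.72 log2 units, with 3 of 25 called lower, Cenpf (-1.39 ± 0.23), Ccnb2 (-1.36 ± 0.28) and Cdc20 (-1.16 ± 0.27), and 13 adjusted over the list alone. Cell cycle genes as a set had a camera adjusted p = 2.84e-12, and adjusted p = 0.427 with an estimated correlation. Of 16 microglia markers 2 fell (2 adjusted over the list alone): P2ry12, a purinergic receptor of resting microglia, at -2.19 ± 0.45 and Siglech at -1.90 ± 0.42. Microglia markers as a set had a camera adjusted p = 0.00615, and adjusted p = 0.696 with an estimated correlation. The other large decreases were Gpr165 at -2.74 ± 0.53 and Adamts16, Nup210, Tacr3, Lrrc55, Car4 and Depdc1a, between -2.11 and -1.47. Neuron and oligodendrocyte markers were also lower in WT HI than WT sham libraries (medians -1.92 and -2.80; camera adjusted p = 0.00193 and 5.47e-04, and adjusted p = 0.674 and 0.660 with an estimated correlation), and WT sham 2 had the highest neuron markers of the 7.

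In this comparison edgeR quasi-likelihood called 271 genes at a Benjamini-Hochberg adjusted p under 0.05, 205 higher and 66 lower, and 15 of 31 lists, of which 3 kept their call with an estimated correlation. Unadjusted fry p-values in WT were 4.91e-05 for matrix proteases and inhibitors, 0.00119 for cytokines and 0.00830 for lysosome genes. They were 0.105 for neutrophil and 0.321 for microglia markers. The share of higher genes was 54.7% with limma-voom, 53.1% in a fit of only the 2 groups and 50.6% with neural and choroid covariates. Of the 10 largest increases 5 kept their calls under all alternatives: Ccl11, Lcn2, Lrg1, Sele and Selp. Of the 10 largest decreases 0 did. The count was sensitive to single libraries: 48, 51 and 57 genes without WT sham 1, 2 or 3, 115, 165 and 154 without WT HI 1, 4 or 5, and 554 without KO sham 1. It was 782 with DESeq2, 3691 with limma-voom, 2443 in a fit of only the 2 groups and 750 without the 5 libraries with high neuron markers, where P2ry12 and Siglech no longer passed.

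**Figure D2:**
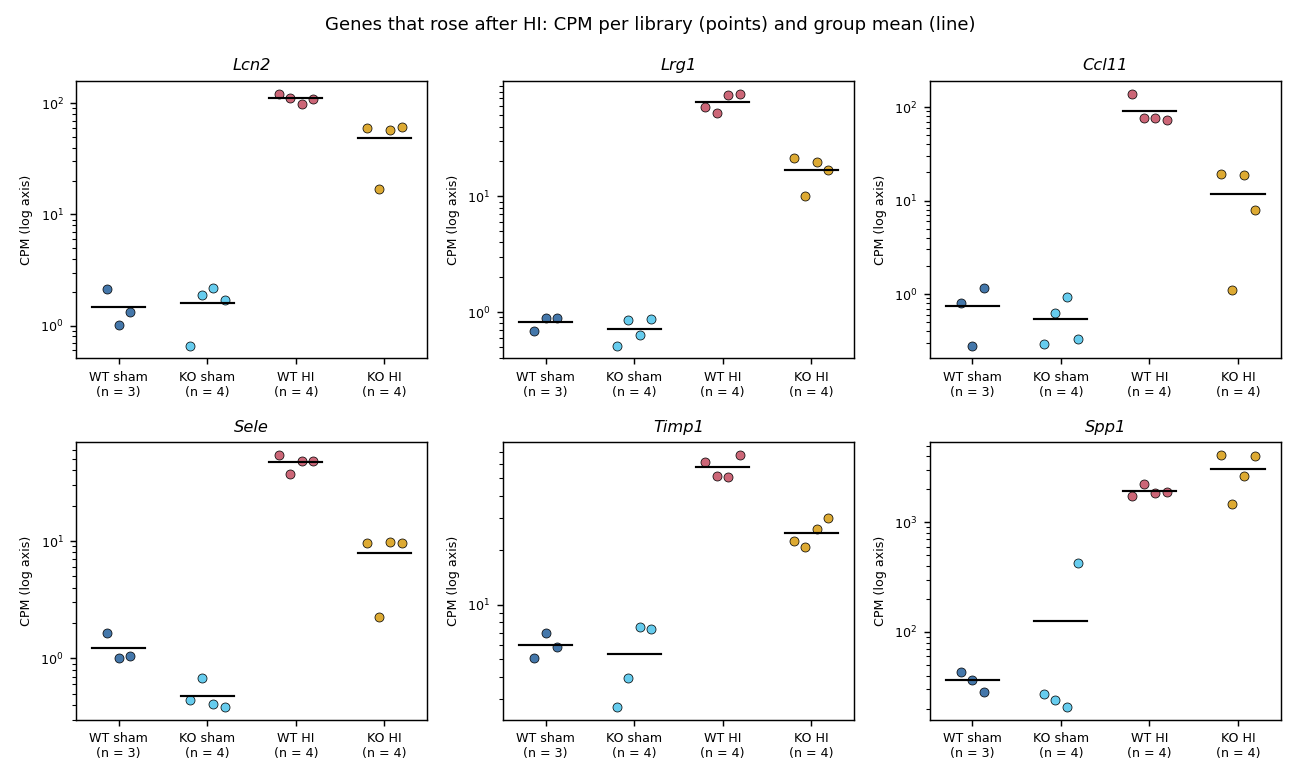
CPM per library on a log axis (points) and group mean (line) for 6 genes that rose after HI in both genotypes, in WT sham (n = 3), KO sham, WT HI and KO HI (n = 4 each). Lrg1 averaged 65.7 CPM in WT HI and 17.0 in KO HI libraries, against 0.82 and 0.72 in the sham groups.

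The second comparison asked the same of KO mice. The largest increases in KO included genes also among the largest in WT, with no gene called for a difference of responses by edgeR (768 at an unadjusted p under 0.05; 22 called by DESeq2, 2 by limma-voom). Lrg1 rose by 4.54 ± 0.27 and Lcn2 by 4.91 ± 0.44 log2 units, as did the myeloid receptors Lilr4b, Lilrb4a (4.67 ± 0.46) and Msr1 (4.72 ± 0.48) and the protease Adam8 (4.81 ± 0.47). Spp1 (4.62 ± 0.94), Ccl11 (4.41 ± 0.76), Prg4 (4.23 ± 0.81) and Il1rn (3.96 ± 0.56) completed the 10 largest increases. The Spp1 value depends on KO sham 6, with 7791 counts against 356 to 422 in the other KO sham libraries and 25449 to 72592 in KO HI. Acta2, smooth muscle actin (Gene ID 11475), fell with 3 other contractile genes, from 1039 ± 489 to 406 ± 121 CPM (SD, n = 4 each).

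Of 27 cytokine, chemokine and NF-κB target genes 13 rose (24 up and 1 down adjusted over the list alone), with Ccl5 at 3.64 ± 0.41, Ccl12, a monocyte chemokine, at 2.79 ± 0.38 and Ptgs2 at 2.75 ± 0.33. The cytokine list as a set had a camera adjusted p = 2.66e-26, and adjusted p = 0.0974 with an estimated correlation. Of 19 lysosome and phagocytosis genes 12 rose (15 up and 1 down adjusted over the list alone), with Lpl at 3.76 ± 0.44, Lgals3 at 3.57 ± 0.38, the cathepsin Ctsl at 1.78 ± 0.27 and Cd63 at 1.08 ± 0.11. Lysosome and phagocytosis genes as a set had a camera adjusted p = 6.33e-24, and adjusted p = 0.0974 with an estimated correlation. Of 16 microglia markers 5 rose (8 adjusted over the list alone), with the complement genes C1qb and C1qa at 1.42 ± 0.33 and 1.21 ± 0.30. Microglia markers as a set had a camera adjusted p = 4.97e-06, and adjusted p = 0.490 with an estimated correlation. Of 14 neutrophil and monocyte markers 5 rose (8 adjusted over the list alone), with Ccr2 at 2.60 ± 0.57 and S100a8 at 3.50 ± 0.80. Neutrophil and monocyte markers as a set had a camera adjusted p = 2.85e-06, and adjusted p = 0.344 with an estimated correlation. Without the 5 libraries with high neuron markers, which leaves 2 KO libraries per group, the edgeR fit called 0 members of the microglia and 0 of the neutrophil list, with medians of 0.89 and 0.93; at unadjusted p under 0.05 it had 7 and 4 of them, and in all libraries DESeq2 called 8 and 6 of them and limma-voom 0 and 0, with 7 and 8 at an unadjusted p under 0.05.

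Of 20 genes of the integrated stress and unfolded protein response 7 rose (10 adjusted over the list alone), among them the endoplasmic reticulum chaperone genes Sdf2l1 (1.82 ± 0.27), Hspa5 (0.98 ± 0.20) and Calr (0.73 ± 0.14), with a camera adjusted p of 1.80e-08 and an adjusted p = 0.0974 with an estimated correlation. Of 28 hypoxia-inducible genes 6 rose (6 up and 1 down adjusted over the list alone), with the lactate transporter Slc16a3 at 2.58 ± 0.42 and Ldha at 0.63 ± 0.11. Hypoxia-inducible genes as a set had a camera adjusted p = 0.0189, and adjusted p = 0.185 with an estimated correlation. Of 16 glycolysis enzymes 3 rose (4 adjusted over the list alone): Pkm, Ldha and Hk2, the last by 1.28 ± 0.31. Glycolysis enzymes as a set had a camera adjusted p = 6.98e-04, and adjusted p = 0.490 with an estimated correlation. Of 19 matrix proteases and inhibitors 7 rose (8 adjusted over the list alone), with Timp1 at 2.21 ± 0.28, Mmp13 at 6.17 ± 0.88 and Mmp12 at 5.16 ± 0.80. The list had a median of 0.25, and its member Mmp3 had 0 counts in each KO sham library and was at least 31.5-fold higher in KO HI, against a floor of 3 counts per library (camera adjusted p = 6.94e-07, and adjusted p = 0.0974 with an estimated correlation). Of 17 p53 targets 3 rose (5 adjusted over the list alone), Pmaip1, Cdkn1a (1.29 ± 0.26) and Bax (0.59 ± 0.13), with a camera adjusted p of 0.00154 and an adjusted p = 0.0974 with an estimated correlation. The heme-degrading enzyme Hmox1 rose by 1.86 ± 0.34; it was 1 of 2 called heat shock list members (2 adjusted over the list alone; camera adjusted p = 0.0242, and adjusted p = 0.397 with an estimated correlation).

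Of 15 smooth muscle and contractile genes 4 fell (12 adjusted over the list alone): Acta2 (-1.35 ± 0.34), Pln (-1.54 ± 0.42), Myocd (-1.46 ± 0.41) and Myl9 (-1.10 ± 0.30), with a camera adjusted p of 4.58e-09 and an adjusted p = 0.344 with an estimated correlation. Of 23 genes of pericyte-endothelial signalling 3 fell, Hey1 (-1.02 ± 0.19), Cdh2 (-0.56 ± 0.11) and S1pr1 (-0.61 ± 0.12), and Lrp1 rose by 0.82 ± 0.16 (7 down and 1 up adjusted over the list alone). Signalling genes as a set had a camera adjusted p = 0.00103, and adjusted p = 0.490 with an estimated correlation. The largest decreases included Susd5 (-2.22 ± 0.37), the olfactory receptor family genes Olfr558 and Olfr78, Adamts16, Insc, Fbln5, an elastic fibre protein, Ptprr, Rcan2 and Lmcd1, the last at -1.49 ± 0.24. The medians of the pericyte and endothelial lists were -0.52 and -0.55 (camera adjusted p = 0.00628 and 0.00105, and adjusted p = 0.694 and 0.618 with an estimated correlation).

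For KO the edgeR quasi-likelihood test called 1041 genes at a Benjamini-Hochberg adjusted p under 0.05, 725 higher and 316 lower, and camera called 20 of 31 lists, none of which kept its call with an estimated correlation. Unadjusted fry p-values in KO were 5.27e-05 for lysosome and phagocytosis genes and 2.13e-04 for cytokines. They were 0.0631 for microglia and 0.196 for endothelial markers. The share of higher genes was 50.7% without KO HI 4, 53.5% without KO sham 1 and 50.5% with neural and choroid covariates. Of the 10 largest increases 6 kept their calls under all alternatives: Adam8, Lcn2, Lilr4b, Lilrb4a, Lrg1 and Msr1. Of the 10 largest decreases 0 did. The count was 355 without KO HI 1, 1592 without KO HI 2, 1927 without KO sham 1, 547 and 658 without KO sham 3 or 4 and 683 without WT sham 2. It was 1932 with DESeq2, 609 with limma-voom, 16 in a fit of only the 2 groups and 2458 without the 5 libraries with high neuron markers. In that last fit, which leaves 2 KO libraries per group, Acta2 and Aif1 no longer passed.

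The third comparison asked how KO cells differed from WT cells without injury. KO sham libraries lacked nearly all transcript of Eno1b (Gene ID 433182), a near-identical copy of the enolase gene Eno1: 1 to 5 counts per KO library against 3507 to 5431 per WT library, a log2 fold change of -10.37 ± 0.79 (edgeR adjusted p = 1.03e-04). Reads of Eno1 and Eno1b can be assigned to either, so this value and that of Eno1 are uncertain. Col28a1 (Gene ID 213945), a collagen gene, had 33 to 177 counts per KO and 1 to 5 per WT sham library (log2 fold change 5.45 ± 0.74, edgeR adjusted p = 0.0410). It was below 10 CPM and is named after its values were seen.

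As sets, pericyte, endothelial and basement membrane genes were lower and microglia and neuron markers higher in KO sham, while smooth muscle and contractile genes had a median of -0.05 (camera adjusted p = 0.131). The pericyte list had a median of -0.73 (camera adjusted p = 8.21e-14, and adjusted p = 0.475 with an estimated correlation), the endothelial list -0.48 (camera adjusted p = 4.15e-11, and adjusted p = 0.475 with an estimated correlation) and the basement membrane list -0.67 (camera adjusted p = 3.56e-13, and adjusted p = 0.475 with an estimated correlation). Microglia markers had a median of 0.69 (camera adjusted p = 1.66e-07, and adjusted p = 0.518 with an estimated correlation) and neuron markers 2.72 (camera adjusted p = 0.00330, and adjusted p = 0.716 with an estimated correlation). Immediate early genes, among them Fosb (-1.30 ± 0.42) and Nr4a1 (-1.41 ± 0.51), had a median of -0.47 (camera adjusted p = 1.86e-08, and adjusted p = 0.475 with an estimated correlation). Single members of these lists did not pass the edgeR threshold over all genes. KO sham 1 stood apart, with pericyte, endothelial and basement membrane lists at 5.76, 7.43 and 7.80 log2 CPM. The other KO sham libraries had 6.87 to 7.49, 8.45 to 8.92 and 8.66 to 9.18, and WT sham 7.38 to 7.93, 8.90 to 9.12 and 9.23 to 9.40. Neuron markers were at 6.30 in KO sham 1 and 0.06 to 3.93 in the other KO sham libraries. Microglia markers went the other way, at 7.39 against 7.96 to 8.19.

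In sham libraries edgeR quasi-likelihood called 2 genes at a Benjamini-Hochberg adjusted p under 0.05, and 1272 genes had an unadjusted p under 0.05 (418 without WT sham 1, 584 without WT sham 3 and 3166 without KO sham 4). Camera called 18 of 31 lists, none of which kept its call with an estimated correlation. Unadjusted fry p-values in sham were 0.0401 for matrix proteases and inhibitors, 0.0501 for pericyte and 0.0755 for endothelial markers. They were 0.0522 for basement membrane genes and 0.101 for microglia markers. DESeq2 called 32 genes, limma-voom 10 and the fit without the 5 libraries with high neuron markers 5. The call of Eno1b ended with limma-voom and without those 5 libraries. Eno1b counts in the sham libraries then left were 5282 and 5431 in WT against 5 and 1 in KO, so the difference stayed large. The call of Col28a1 ended without WT sham 1, 2 or 3, without KO sham 3, 4 or 6 and without WT HI 1, 2, 4 or 5. It also ended without KO HI 1 or 2, in a fit of only the 2 groups and with the replicate number as a block.

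The fourth comparison asked how KO and WT cells differed 24 h after HI. Microglial transcripts were higher and vessel-wall transcripts lower in KO HI libraries. All 16 microglia markers were called higher, with Aif1 (Gene ID 11629) higher by 2.08 ± 0.29 log2 units, and Pdgfrb (Gene ID 18596) was at 356 ± 174 against 925 ± 125 CPM (SD, n = 4 each). Among the 10 largest decreases were Sele by -2.58 ± 0.37, Selp by -2.25 ± 0.46, Ccl11 by -2.95 ± 0.65, Il6 by -2.66 ± 0.52 and Cxcl1 by -2.24 ± 0.51 log2 units, while the chemokine Ccl12 was higher by 1.63 ± 0.36. The fructose transporter gene Slc2a5, expressed by microglia, was higher by 4.17 ± 0.60 and the protease gene Ctse by 5.54 ± 1.39.

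The 16 microglia markers had a median of 1.67, with P2ry12 and Siglech at 2.45 ± 0.43 and 2.45 ± 0.41 and the transcription factor Sall1 at 1.59 ± 0.29 (16 adjusted over the list alone). Microglia markers as a set had a camera adjusted p = 1.33e-19, and adjusted p = 0.368 with an estimated correlation. Of 8 border macrophage markers 5 were higher (8 adjusted over the list alone), with Mrc1 at 1.33 ± 0.29 and Pf4 at 1.43 ± 0.33. Border macrophage markers as a set had a camera adjusted p = 2.62e-05, and adjusted p = 0.429 with an estimated correlation. Of 19 lysosome and phagocytosis genes 13 were higher and 1 lower (16 up and 1 down adjusted over the list alone), with Ctss at 1.79 ± 0.32, Hexa at 0.99 ± 0.19 and Npc2 at 0.83 ± 0.12. Lysosome and phagocytosis genes as a set had a camera adjusted p = 7.06e-10, and adjusted p = 0.368 with an estimated correlation. The other large increases were Neurl1a (2.69 ± 0.72), Matk, Smim10l2a, Crybb1, Hpgd, an enzyme that degrades prostaglandins (2.39 ± 0.29), and Kif21b. Neuron and oligodendrocyte markers had medians of 3.53 and 4.25 in the same comparison. Of 15 neuron markers 0 were called over all genes (14 up adjusted over the list alone), and of 15 oligodendrocyte markers also 0 (12 up and 1 down). The sets had camera adjusted p = 9.92e-04 and 0.00645, and adjusted p = 0.747 and 0.747 with an estimated correlation. Neuron markers averaged 3.74 and 5.67 log2 CPM in KO HI 2 and 3. They averaged 0.67 and 0.68 in KO HI 1 and 4, within the 0.14 to 0.92 of WT HI.

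Of 20 pericyte markers 8 were lower (18 adjusted over the list alone), with Pdgfrb at -1.38 ± 0.35, Mcam at -1.44 ± 0.32 and Cspg4, the proteoglycan NG2, at -1.11 ± 0.30. Pericyte markers as a set had a camera adjusted p = 4.15e-12, and adjusted p = 0.388 with an estimated correlation. Of 20 endothelial markers 13 were lower (19 adjusted over the list alone), with Vwf at -1.27 ± 0.28 and Pecam1 at -1.26 ± 0.29. Endothelial markers as a set had a camera adjusted p = 1.75e-12, and adjusted p = 0.388 with an estimated correlation. Of 15 smooth muscle and contractile genes 6 were lower (11 adjusted over the list alone), with Des at -1.20 ± 0.31 and Smtn at -1.01 ± 0.28. Smooth muscle and contractile genes as a set had a camera adjusted p = 4.29e-07, and adjusted p = 0.429 with an estimated correlation. Of 24 basement membrane and matrix genes 13 were lower (21 adjusted over the list alone), with Loxl2, a collagen crosslinker, at -1.63 ± 0.32 and the heparan sulfate proteoglycan Hspg2 at -1.17 ± 0.27. Basement membrane genes as a set had a camera adjusted p = 1.89e-14, and adjusted p = 0.368 with an estimated correlation. Of 23 genes of pericyte-endothelial signalling 12 were lower and 1 higher (15 down and 2 up adjusted over the list alone), with the vasoconstrictor gene Edn1 at -1.86 ± 0.31, Hey1 at -0.96 ± 0.19 and S1pr1 at -0.63 ± 0.12. Signalling genes as a set had a camera adjusted p = 3.49e-08, and adjusted p = 0.368 with an estimated correlation. In the same comparison the microglia markers were higher, so a shift between cell types would move all of these lists.

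Of 19 matrix proteases and inhibitors 8 were lower (8 adjusted over the list alone), with Adamts4 at -2.17 ± 0.32 and Timp1 at -1.21 ± 0.27. Matrix proteases and inhibitors as a set had a camera adjusted p = 3.00e-05, and adjusted p = 0.368 with an estimated correlation. Of 27 cytokine, chemokine and NF-κB target genes 5 were lower and 1 higher (7 down and 1 up adjusted over the list alone): Ptgs2 was lower by -1.76 ± 0.31 and the receptor Osmr by -1.32 ± 0.30, and Ccl12 was higher. The cytokine list as a set had a camera adjusted p = 0.0670, and adjusted p = 0.747 with an estimated correlation. The other large decreases were Eno1b (-10.01 ± 0.80), Scgb3a1, Tfpi2, a protease inhibitor (-2.28 ± 0.39), and Pla1a. Of 28 hypoxia-inducible genes 4 were higher, with Pfkfb4 at 1.08 ± 0.17 and Pdk1 at 0.59 ± 0.09, and 5 lower, with Bhlhe40 at -1.46 ± 0.20 and Ddit4 at -1.05 ± 0.18 (7 up and 6 down adjusted over the list alone). The median and the mean of that list were both -0.02 while its test pointed up (camera adjusted p = 0.971). Of 16 glycolysis enzymes 4 were higher (4 adjusted over the list alone), with Hk2 at 1.46 ± 0.32 (camera adjusted p = 5.70e-04, and adjusted p = 0.429 with an estimated correlation), and 1 of the 4 was Eno1, which shares reads with Eno1b. The glycolysis list averaged 8.29 and 8.48 log2 CPM in KO HI 2 and 3, the KO HI libraries with high neuron markers, 7.92 and 7.69 in KO HI 1 and 4, and 7.40 to 7.67 in WT HI.

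Other lists were also compared between genotypes after HI. Of 12 antigen presentation genes 4 were higher (4 adjusted over the list alone), with B2m at 0.93 ± 0.19 and Cd74 at 1.15 ± 0.28. Antigen presentation genes as a set had a camera adjusted p = 0.0267, and adjusted p = 0.747 with an estimated correlation. Of 25 cell cycle genes 2 were higher (2 adjusted over the list alone), E2f1 at 0.66 ± 0.14 and Pcna at 0.55 ± 0.16. Cell cycle genes as a set had a camera adjusted p = 0.00496, and adjusted p = 0.747 with an estimated correlation. The 35 nuclear-encoded respiratory chain genes had a median of 0.34, with 35 of 35 positive and none past the edgeR threshold (camera adjusted p = 1.92e-04, and adjusted p = 0.747 with an estimated correlation). That median was 0.072 without the 5 libraries with high neuron markers, and the list averaged 7.26 and 7.39 log2 CPM in KO HI 2 and 3, 6.85 and 6.70 in KO HI 1 and 4, and 6.61 to 6.71 in WT HI. Of 15 fibroblast markers 1 was lower, Mgp at -1.21 ± 0.34 (5 adjusted over the list alone), with a list median of -1.013. Fibroblast markers as a set had a camera adjusted p = 4.79e-06, and adjusted p = 0.429 with an estimated correlation. Near Mir210 4 of 34 genes were lower (4 adjusted over the list alone), among them Ifitm1 at -1.52 ± 0.33, Ifitm2 at -0.85 ± 0.19 and Ifitm3 at -0.93 ± 0.22, while the list had a median of 0.06 and its test pointed down (camera adjusted p = 0.241). Of 17 p53 targets Phlda3 (-1.20 ± 0.21) and Fas (-0.94 ± 0.25) were lower (2 adjusted over the list alone), with a list median of 0.12, a mean of -0.07 and a test that pointed down (camera adjusted p = 0.677). Of 19 immediate early genes 3 were lower (3 adjusted over the list alone), with Ccn1 at -2.00 ± 0.42.

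After HI edgeR quasi-likelihood called 1844 genes between genotypes at a Benjamini-Hochberg adjusted p under 0.05, 885 higher and 959 lower in KO, and camera called 16 of 31 lists, none of which kept its call with an estimated correlation. Unadjusted fry p-values after HI were 2.8e-04 for microglia markers, 7.9e-04 for lysosome genes and 0.00228 for basement membrane genes. They were 0.00445 for endothelial, 0.00552 for pericyte and 0.123 for neuron markers. The share of higher genes was 35.0% of 2714 without KO HI 4 and 59.7% without KO HI 3. Without the 5 libraries with high neuron markers edgeR called 3440 genes, 1601 of them among the 1844, and microglia markers stayed at 16 of 16 called with a median of 1.98, while 18 of 20 endothelial and 9 of 20 pericyte markers were lower. With microglia markers as a further covariate it called 1 gene, Eno1b, and 404 of the 1844 changed sign; that covariate itself separated the groups. DESeq2 called 3399 genes and limma-voom 3647, and the count was 481, 538 and 558 without WT HI 1, 4 or 5, 669 and 1028 without KO HI 1 or 3 and 3605 without KO sham 1. Of the 10 largest increases 0 kept their calls under all alternatives, and of the 10 largest decreases also 0. With the replicate block and the microglia covariate set aside, 5 increases and 5 decreases kept their calls.

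Published targets of miR-210 and genes with a seed site showed no shift as sets that passed the camera test in the main fit. Small shifts may have been missed. At 2-fold the simulation recovered 40% of single changed genes in sham and 55% after HI, and smaller changes were not simulated. Of 19 tested targets edgeR called 0 in KO against WT after HI, with 5 at an unadjusted p under 0.05; DESeq2 called 0 and limma-voom 4. The closest were Acvr1b (0.43 ± 0.16, adjusted p = 0.101) and Ndufa4, a respiratory chain subunit (0.83 ± 0.34, adjusted p = 0.122), and the list had a median of 0.14 (camera adjusted p = 0.568). In sham the edgeR test also called 0 of the 19, with 3 at an unadjusted p under 0.05; DESeq2 and limma-voom called 0 and 0, Acvr1b was at 0.60 ± 0.18 and the list had a median of 0.13 (camera adjusted p = 0.463). In KO the target Ptpn1 rose by 0.71 ± 0.14 after HI, and in WT it was at 0.62 ± 0.15 (edgeR adjusted p = 0.0614). The 553 genes with an ACGCACA site in the 3-prime UTR differed from the 14102 without one by a mean of 0.13 log2 units in sham and 0.14 after HI and did not pass the camera test in either. With neural and choroid covariates the difference after HI was -0.018 (miR-210 seed-site genes, KO against WT in HI), and the medians after HI with and without a site were 0.063 and 0.062. Of the 59 other 7mers of the same composition, 14 and 12 gave a difference at least as high. The 70 genes with the longer site ACGCACAA differed by 0.16 and 0.15 and did not pass it either.

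**Figure D3:**
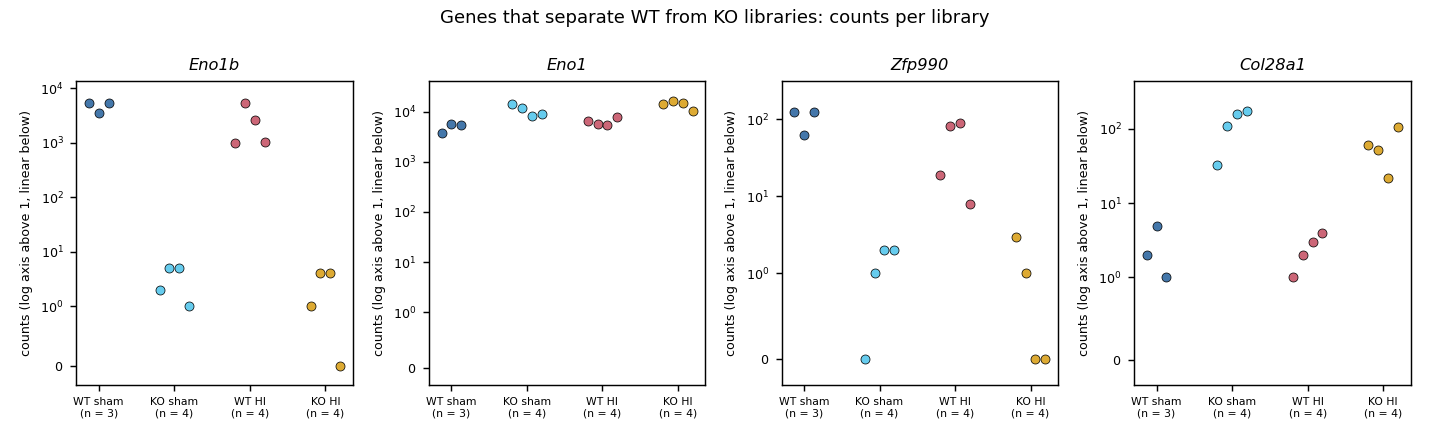
Expected counts per library (points; log axis above 1, linear below) of Eno1b, Eno1, Zfp990 and Col28a1 in WT sham (n = 3), KO sham, WT HI and KO HI (n = 4 each). Eno1b lay between 1008 and 5431 counts in WT libraries and between 0 and 5 in KO libraries.

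The last comparison asked whether the response to HI differed between genotypes. Across the 14853 genes the responses of KO and WT had a Pearson r of 0.629 and a Spearman rho of 0.508, with genes as points that are not independent replicates. The Pearson r was 0.289 without KO sham 1 and 0.386 without a filter on low counts. Of the 271 genes called in WT, 262 moved in the same direction in KO. Called higher in both were 129 genes, against 10.01 if the calls were independent, and 23 were lower in both, against 1.404. Both contrasts come from 1 fit that shares the spread of each gene, so calls can coincide more often than under independence. The response of Lrg1 was 6.31 ± 0.32 log2 units in WT and 4.54 ± 0.27 in KO, and that of Lcn2 6.22 ± 0.53 and 4.91 ± 0.44; the differences were -1.77 ± 0.37 and -1.31 ± 0.59 (edgeR adjusted p = 0.704 and 0.932).

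The edgeR test of the difference of responses called 0 genes, with 768 at an unadjusted p under 0.05 and a smallest adjusted p of 0.265. The 768 became 458 and 442 without WT sham 1 or 2, 474, 1251 and 473 without WT HI 1, 2 or 5, 1559 without KO sham 1 and 495 and 1203 without KO HI 1 or 2. For the difference DESeq2 called 22 genes and limma-voom 2, and with edgeR 2 and 1 genes were called without WT HI 2 or KO sham 6. As sets, 16 of 31 lists differed with the preset correlation, and the same test with an estimated correlation called 0 of 31. By p-value microglia markers came first (median 0.94, camera adjusted p = 7.62e-18, and adjusted p = 0.447 with an estimated correlation), with P2ry12 at 1.89 ± 0.61 (adjusted p = 0.834), followed by the cell cycle list (0.52, camera adjusted p = 3.03e-11, and adjusted p = 0.539 with an estimated correlation). The medians of oligodendrocyte (1.67, camera adjusted p = 0.0600), neuron (1.32, camera adjusted p = 0.0284) and border macrophage markers (1.04, camera adjusted p = 8.32e-07) were also above 0, each with an adjusted p above 0.05 with an estimated correlation. One list was not tested against another. Unadjusted fry p-values for the difference were 0.0463 for microglia markers, 0.00486 for genes near Mir210, 0.136 for smooth muscle genes and 0.351 for endothelial markers. Smooth muscle and contractile genes responded lower in KO by a median of -0.85 (camera adjusted p = 6.59e-08, and adjusted p = 0.539 with an estimated correlation), with Acta2 at -1.13 ± 0.49 (adjusted p = 0.932). The genotype difference in sham and that after HI had a Pearson r of 0.820 and a Spearman rho of 0.739 across genes; they share no libraries, and 1732 of the 1844 genes called after HI had the same sign in sham.

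**Figure D4:**
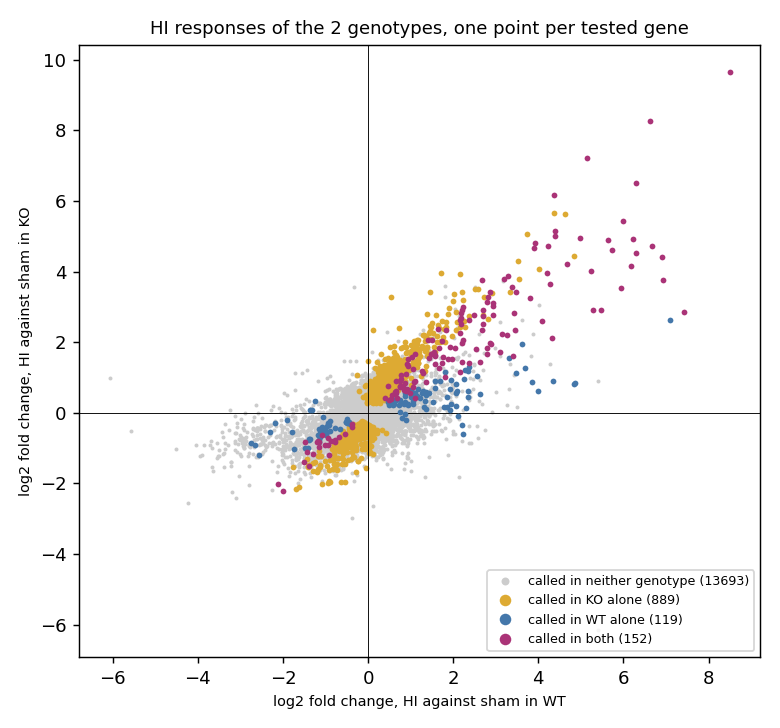
Log2 fold change of HI against sham in KO (vertical axis) against that in WT (horizontal axis) for each of the 14853 tested genes, coloured by the genotypes in which the gene was called. 152 genes were called in both, 889 in KO alone, 119 in WT alone and 13693 in neither.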

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

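The tests of a lower share of PDGFRβ-positive cells, of reads shared between Eno1 and Eno1b, of a strain-derived stretch, of a cell mix in the genes of that stretch and in Eno1b, of a weaker injury, and the choice of the endothelial activation genes, were made after the results were seen.

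Single libraries lay far from the others of their group in 9 of 111 tests, each of 1 measure in 1 group of 4 libraries. Chance alone flags about 1 in 20 tests, here 5.55, but the measures are not independent of each other. WT sham had fewer libraries and was not tested. The ratio given is the gap to the nearest library over the range of the group, each above the 95% critical value of Dixon's test. WT HI 2 had higher microglia markers (7.78 log2 CPM against 6.41 to 6.52, ratio 0.923), higher lysosome and phagocytosis genes (8.88 against 8.17 to 8.26, ratio 0.872) and lower basement membrane genes (9.12 against 9.54 to 9.59, ratio 0.899). KO sham 1 had fewer total counts (15436376 against 17017223 to 17306041, ratio 0.846) and lower matrix proteases and inhibitors (3.96 against 4.29 to 4.35, ratio 0.850). KO sham 4 had fewer genes above 0 (15907 against 16323 to 16344, ratio 0.952), and KO sham 6 had a higher Spp1 level (8.74 log2 CPM against 4.37 to 4.78, ratio 0.906). WT HI 1 had higher heat shock genes (7.06 against 6.88 to 6.90, ratio 0.877), and KO HI 3 lower endothelial markers (7.27 against 8.16 to 8.28, ratio 0.882).

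The response to HI differed between KO and WT in 16 of 31 lists by camera with the preset correlation, with adjusted p between 0.447 and 0.795 for these lists with an estimated correlation. The response was higher in KO, by the list median in log2 units and with the camera adjusted p, for microglia markers (0.94, 7.62e-18), border macrophage markers (1.04, 8.32e-07), neutrophil and monocyte markers (0.50, 0.0302), neuron markers (1.32, 0.0284) and antigen presentation (0.18, 0.0257). It was also higher for the cell cycle (0.52, 3.03e-11), the integrated stress and unfolded protein response (0.32, 0.00142), immediate early genes (0.52, 0.00184) and lysosome and phagocytosis (0.43, 9.74e-08). It was lower in KO for pericyte markers (-0.27, 0.00992), smooth muscle and contractile genes (-0.85, 6.59e-08), endothelial markers (-0.47, 2.67e-04), basement membrane and matrix (-0.45, 8.49e-05), matrix proteases and inhibitors (-0.16, 0.0284), pericyte-endothelial signalling (-0.44, 0.00361) and genes near Mir210 (-0.15, 0.0284).

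Other splits of the same libraries into groups of the same sizes were compared with the real one. In WT 1 of 35 splits, the real one, gave 271 or more genes after HI (highest other 11). In sham 1 of 35 gave 2 or more genes between genotypes (highest other 0), and after HI 1 of 35 gave 1844 or more (highest other 35). A share of 1 in 35 is the smallest that these splits can give, and it was not adjusted for the number of comparisons. Chance is thus unlikely for these 3 counts but is not excluded. In KO 3 of 35 splits gave 1041 or more genes after HI (highest other 5594), so chance cannot be excluded there; the highest split set KO sham 1 and 3 with KO HI 2 and 3, the KO libraries with high neuron markers, against the rest, which points to a structure of the samples. For the difference of responses 100 of 100 splits gave at least the 0 genes called by edgeR (768 at an unadjusted p under 0.05; 22 by DESeq2, 2 by limma-voom; highest other 1024), as any split must, so this comparison says nothing about chance. For the counts of lists chance cannot be excluded in any of the 5 comparisons: 15 of 35 splits gave 15 or more lists in WT (highest other 20), 4 of 35 gave 20 or more in KO (21), 16 of 35 gave 18 or more in sham (22), 17 of 35 gave 16 or more after HI (19) and 45 of 100 gave 16 or more for the difference (21).

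KO libraries had higher microglial and lower mural and endothelial transcripts than WT libraries after HI. Neural tissue carried into some libraries was argued against as the whole source: without the 5 libraries with the highest neuron markers the gap between the microglia and endothelial medians was 2.83, against 2.67 in all libraries. A lower share of PDGFRβ-positive cells with all other cells alike would raise endothelial markers, but these had a median of -1.002 and were lower in 20 of 20. These values were known when the prediction was written, so this is no independent test. They speak only against that narrow form. A lower share of PDGFRβ-positive and endothelial cells together was not tested and stays open. A difference between the preparations that is present without injury stays open: the microglia minus endothelial level was already 1.32 higher in KO sham (exact permutation p = 0.0286, the smallest that 35 splits can give) and 2.88 higher after HI. The genotype itself, which the design names, stays open as a biological source, as untested.

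Between genotypes 192 genes, 1.29% of those tested, separated all KO from all WT libraries, against 0.0311% by chance, and 42 of them did so by at least 2-fold in both treatments (20 higher and 22 lower in KO). Reads shared between Eno1 and Eno1b may explain part of this, since their summed level differed by 0.47 log2 units (exact permutation p = 0.0283) and Eno1 alone by 1.16. The exact permutation p of Eno1 alone, 3.11e-04, was fixed by choosing genes that separate all libraries and is no test. The p of the sum rests in part on the same choice and is no independent test either. In KO libraries the sum, 740.1 CPM, was almost all Eno1, 739.9 CPM. A stretch of chromosome from another strain background, left from the making of the KO line, is a candidate explanation for another part: 7 of the 42 (Padi2, Zfp990, Zfp985, Masp2, Rbp7, Slc2a5 and Eno1, named after their values were seen) lay within 100 consecutive tested genes, on another chromosome than Mir210, against a median of 3 and a highest of 6 in 10000 random draws (permutation p = 1.000e-04, the smallest these draws can give). Without Eno1 the stretch held 6, with a highest of 7 in the draws (permutation p = 3.000e-04), and without Eno1 and Slc2a5 it held 5, with a highest of 6 (permutation p = 0.0047). The draws placed genes independently, while neighbouring genes such as Zfp990 and Zfp985 may vary together, so these p-values may be too small. Near Mir210 itself the list had a median of 0.04 in sham (camera adjusted p = 0.677) and 0.06 after HI (camera adjusted p = 0.241). With neural, choroid and microglia marker levels as covariates the median size of the differences after HI was 1.12 for the 42 genes (1.82 without; ratio 0.617, 95% interval 0.322 to 0.710 from 10000 resamplings of the genes) and 2.03 for the 7 (2.64 without; ratio 0.771, 95% interval 0.487 to 1.19). As sets, these genes leave a different cell mix open, since the covariates differ between the genotypes too. For Eno1b it was argued against: its difference after HI was -11.75 ± 0.91 with the covariates and -10.01 ± 0.80 without, and stayed past the edgeR threshold. Zfp990 (-6.75 ± 1.48, from -5.45 ± 0.99) and Col28a1 (5.72 ± 1.01, from 4.53 ± 0.64) did not shrink either, but their calls ended (edgeR adjusted p = 0.604 and 0.435) as their standard errors grew, while the microglial gene Slc2a5 fell to 2.03 ± 1.17 from 4.17 ± 0.60.

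The mean level of 8 endothelial activation genes, chosen after some of them were seen to be lower, differed by -1.401 log2 units between KO and WT after HI, so that difference was not tested. Of the 8, Sele, Selp, Ackr1, Lrg1 and Ch25h were lower by edgeR, and Icam1, Vcam1 and Csf3 did not pass (edgeR adjusted p = 0.214, 0.646 and 0.369). A lower share of vessel RNA cannot be told apart from lower activation, since relative to the endothelial markers the level differed by -0.36 (exact permutation p = 0.486) with 4 libraries per group. A weaker injury in the KO animals cannot be told apart either: the response of the lysosome and phagocytosis list was 0.43 higher in KO, but microglia express these genes too and microglial transcripts were higher in KO.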

How the results depend on the processing

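The fit without 5 libraries and the fits with marker levels as covariates were chosen after the results were seen; the other alternatives were planned. Of the values of single genes under the alternatives, 4418 kept their direction and side of the threshold, 979 were no longer past it, 14 newly passed it and 12 changed sign. The order below is HI against sham in WT, HI against sham in KO, KO against WT in sham, KO against WT after HI, and the difference of responses, with 271, 1041, 2, 1844 and 0 genes by edgeR (768 at an unadjusted p under 0.05 for the last). DESeq2 called 782, 1932, 32, 3399 and 22 genes and limma-voom 3691, 609, 10, 3647 and 2. RLE size factors gave 308, 1149, 2, 2002 and 0 genes and the stricter filter 275, 1059, 2, 1904 and 0.

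A fit of only the 2 groups called 2443, 16 and 1 genes in the first 3. The count rose in WT and fell in KO, so fewer samples alone do not account for both changes. The main fit shares 1 spread per gene over all 4 groups, so each comparison also depends on the spread of the other groups. Replicates of a group were compared by chi-square per degree of freedom, which is near 1 for counting error alone. It ran from 11.3 to 46.7 in WT and from 44.6 to 384 in KO. With the replicate number as a block the first 4 gave 16, 73, 1 and 21 genes. Deviations from the group means correlated from -0.78 to 0.79 between libraries of the same number. The negative values, -0.78 and -0.61, both involve KO sham 1, which had the highest neuron markers. These correlations cannot settle whether the numbers mark shared batches, which the labels do not name. Without the 5 libraries with high neuron markers the first 4 gave 750, 2458, 5 and 3440 genes, and 11 lists were called in sham in place of 18. Neural and choroid marker levels as covariates gave 1600, 2675 and 15 genes in the first 3 and 8 for the difference. With microglia markers added, 1726 genes were called in WT and 1 between genotypes after HI, and 7 lists for the difference in place of 16; this covariate separates the genotypes after HI, so the fit removes part of any genotype effect.

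The correlation of HI responses of KO and WT across genes was 0.51 with limma-voom and 0.386 without a filter, against 0.629, and 0.289 to 0.687 leaving out single libraries (lowest without KO sham 1). The mean shift of miR-210 seed-site genes, KO against WT in HI, was -0.018 with neural and choroid covariates, against 0.14. With microglia markers added, these differences between genotypes after HI changed sign: Actg2 1.14, Ccl12 -0.12, Hk2 -0.059, Itgam -0.13, Kif21b -0.051, Mgp 0.034, Pcna -0.094, Phgdh -0.32, Ptpn1 -0.15, Sall1 -0.011, Sdf2l1 -0.13 and Tpm1 0.40. The cause of these changes was not tested.

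Leaving out single libraries gave 48 to 554 genes in WT, 355 to 1927 in KO, 1 to 2 in sham, 481 to 3605 after HI and 0 to 2 for the difference. The lists called ranged over 12 to 17, 17 to 22, 12 to 20, 15 to 17 and 9 to 19 in the same order. Depth ran from 15436376 counts in KO sham 1 to 18118697 in KO HI 1 and limits genes near the floor, such as Mmp3 in sham.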

Other observations

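The genes in this part were chosen after the results were seen.

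Transcripts of neurons and of myelin were concentrated in a few libraries of different groups. The first principal component held 57.9% of the variance and the second 13.6%. Across the libraries the first component correlated with the mean level of the neural markers (r = 0.987). The largest share of the variance thus followed the neural marker level, which was uneven within groups and bears on each comparison. Neurod6, a transcription factor of cortical neurons, had 142 counts in KO sham 1 and 115 in KO HI 3, against 0 to 26 in the other libraries, and the myelin gene Mog had 132 and 59, against 0 to 32.

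Ttr counts were 888515 in KO HI 2 and 450867 in KO sham 3, and 389 in WT HI 1 and 2111 in KO sham 4. Morf4l1b ran from 954 to 1581 counts in WT sham libraries and from 267 to 352 in KO sham libraries, and H2-T24 from 53 to 79 and from 125 to 313. After HI Morf4l1b had 869 counts in WT HI 2 and 292 to 327 in the other WT HI libraries.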
